A study of Mus musculus with 8 samples.

How the data were processed

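Total RNA from the epididymal fat of 8 male C57BL/6J mice was hybridized to 1-colour oligonucleotide arrays with 45101 probe sets, 1 array per mouse (per the series design text). The mice formed 4 groups of 2. Chow mice ate a diet with 10% of calories from fat, and the others a high-fat diet (HFD) with 30%, both for 24 weeks. The HFD mice were then randomized to telmisartan or candesartan in drinking water (3 mg/kg/day) or no drug for the next 5 weeks (per the series design text). Groups were taken from the sample titles. The replicate numbers of the labels stand for separate mice within a group, and no source pairs mice across groups. Over the genes tested, the log2 differences between replicates 1 and 2 correlated between groups at −0.041 (chow with candesartan) to 0.206 (telmisartan with candesartan). A factor shared by arrays of the same number is therefore not excluded.

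The deposited values are a linear signal intensity per probe set, made by the authors with the GeneChip Analysis Suite software of the array maker (per the series design text). The version of the summary algorithm and the scaling are not given in the sources used here. The presence calls and comparison analysis that the text names are not in the deposited table, and were not used. The table held 0 negative values and 0 columns of other samples. The 2%-trimmed mean signal differed by up to 1.48 times between arrays, so the arrays were scaled to a common trimmed mean. The series states no scan date or batch. After scaling, the mean log2 signal of the 18 hybridization spike-in probe sets on any array lay within 0.144 of its mean over the arrays.

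Of the 45101 probe sets, 64 are array controls and 9160 are not listed in the probe annotation. Of the probe sets listed there, 34958 have 1 gene symbol and 932 have several. An updated gene table held the gene identifiers of 34754 of the single-symbol probe sets and changed 0 symbols. Scaled signals under 6.69, the 20th percentile of all values, were set to that floor, and log2 was taken. Probe sets with a mean log2 signal over the 8 arrays at or above the 50th percentile were kept (22519). For each gene the probe set with the highest mean was used, among those with 1 symbol, which left 11232 genes. Of these, 5147 had more than 1 probe set past the filter and 12 had an array at the floor.

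Differences were tested with limma 3.58.1 in R 4.3.3 (figures drawn with Python 3.11.15). The model had 4 group means, 4 residual degrees of freedom between arrays and moderated variances with an intensity trend. Tests were two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Intervals are 95% confidence intervals from the same model. Its median interval reached 0.44 on the log2 scale to each side of the estimate. The 2 arrays per group limit the precision. An exact permutation test of 2 arrays against 2 could not reach 0.05: the chance that such arrays do not overlap is 33.3% per gene, which is also the smallest p it allows.

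The comparisons were HFD with chow, each drug with HFD, telmisartan with candesartan, and each drug group with chow. The comparison of the drugs is also the test of the difference between their effects on HFD. A total of 31 gene lists were fixed, and 26 had the 4 tested members that a test needed. List shifts were tested with limma's camera (preset inter-gene correlation 0.01, variance trend on), adjusted over the lists of a comparison, with camera under an estimated correlation and fry beside it. The value of a list is the median log2 fold change of its members. Medians were also ranked among those of random lists of equally bright genes, a step added after the data were seen. The focal lists were pan macrophage, M1 and CD11c macrophage, M2 macrophage and adipocyte identity.

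Genes were named by a rule. It takes, per comparison, the 8 called genes with the largest rise and the 8 with the largest fall whose arrays do not overlap, clone names skipped. If fewer than 3 pass in a direction, it takes the 3 with the smallest p as not passing. It adds the 3 members with the smallest p of each focal list and of each other list past its threshold. Always named, where measured, are Adgre1, Itgax, Mrc1, Arg1, Cd163, Ccl2, Tnf, Adipoq, Lep, Pparg, Agt and Agtr1a. Further genes in the text are marked as chosen after their values were seen.

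The reversal of the diet effect was measured as the share of diet-called genes whose drug effect has the opposite sign, and as the covariance of both effects over all genes. Both were set against 100 simulations of unchanged groups with independent genes.

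The groups, tests, lists, the rule for named genes and the first set of alternative settings were fixed before the data were examined. These settings were quantile normalization, median centring, a floor at the 5th percentile, a pseudocount in place of the floor, no filter, a filter at the 70th percentile, variances without the trend or with robust moderation, only the 2 groups compared, a replicate block, all probe sets, other thresholds, and leaving out each array in turn. A group left with 1 array was assumed to vary like the others. Cyclic loess normalization, separate HFD arrays for the reversal, and the same alternatives for lists other than the focal ones were added after the data were seen.

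The model was tested on simulated data with 8 arrays and, for each gene, 1 spread in all groups. The real groups differ in spread, so the shares below need not hold for them. Of 67 genes changed 2-fold, 41.8% were called in HFD against chow, 49.3% in telmisartan against HFD, 47.8% in candesartan against HFD and 52.2% in telmisartan against candesartan. Of 66 genes changed 4-fold, 92.4%, 80.3%, 87.9% and 90.9% were called in the same order. At 1.5-fold the highest of the 4 shares was 8.96%. The 4 runs used the same setting, so their shares differ by random draws and do not rank the comparisons. The changed genes planted in each run also affect the adjusted p, so the shares need not hold where few genes change. Among the unchanged genes, at most 4 of 10638 were called. Simulated lists of independent genes shifted by 0.5 were called in 20 of 20 cases, and at most 1 of 80 unshifted lists was. Camera with an estimated correlation and fry were not run on these lists. How often they find a true shift is thus not known here.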

Results

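RNA of epididymal fat, the visceral fat pad beside the testis, was measured in 8 male mice with 1 array each. The 4 groups held 2 mice each: chow, high-fat diet (HFD), HFD with telmisartan and HFD with candesartan. Both drugs block the receptor through which angiotensin II raises blood pressure, and were given at the same dose for the same 5 weeks. The 2%-trimmed mean signal of the arrays was 265 and 234 for chow, 248 and 211 for HFD, 214 and 178 for telmisartan, and 237 and 228 for candesartan. Between 18.6% and 22.4% of the values of an array lay at the floor. The ratio of the 3' to the 5' probe sets of actin was 1.18 to 1.22 on all 8 arrays, and that of Gapdh was 0.696 to 0.773. Over the 11232 genes tested, the SD of the log2 difference between the 2 arrays of a group was 0.445 for chow, 0.273 for HFD, 0.484 for telmisartan and 0.314 for candesartan. The first principal component (53.1% of the variance) placed the chow arrays at −43.3 and −40.4 and the HFD arrays at 16.5 and 16.9. Telmisartan array 1 lay between them at −2.99, telmisartan array 2 at 26.0, and the candesartan arrays at 9.93 and 17.3. Of the genes that mark epididymis and testis, neighbours of the fat pad, 0 and 0 were bright enough to be tested.

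The first comparison, HFD with chow, asks what the diet did to the fat. Pan macrophage genes rose together, while M2 macrophage genes went both ways. The signal of Adgre1, which encodes the macrophage marker F4/80, went from 640.2 ± 28.1 to 2631 ± 2.31 (SD, n = 2 each), and that of Itgax, which encodes CD11c, from 206 ± 15.9 to 1774 ± 302. Genes of lipid-laden macrophages and lysosomes rose with them, among them Gpnmb, Atp6v0d2 and the macrophage elastase Mmp12, each by more than 5 on the log2 scale. Slc2a4, the insulin-responsive glucose transporter GLUT4, fell (1644 ± 40.5 to 507 ± 56.4), and the lipogenic, mitochondrial and endothelial lists were lower by camera, with 3 of 21, 4 of 30 and 4 of 14 members called. No list call of this comparison held with an estimated correlation between genes (adjusted p 0.402 to 0.676), while 5 held with fry, the pan macrophage list among them. The lipogenic list was at −0.15 without chow array 1. Adipoq, which encodes adiponectin, was 16419 ± 1409 and 16230 ± 826 (log2 change −0.01, 95% CI −0.26 to 0.23, adjusted p 0.951).

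limma called 909 of 11232 genes, 578 higher and 331 lower with HFD. At least 2-fold changes made up 381 of the rises and 134 of the falls. At an unadjusted p under 0.05 there were 2710 genes, against 562 by chance. The 2 arrays of HFD did not overlap those of chow for 58.1% of genes, against 33.3% by chance. All groups share 1 estimate of the spread, so the count can change when an array of another group is left out. The telmisartan pair, which differed most, leaves that estimate when either of its arrays does. The count was 510 without chow array 1, 182 without HFD array 1, 165 without HFD array 2, 1589 without telmisartan array 1, 1611 without telmisartan array 2, 533 without candesartan array 1 and 535 without candesartan array 2. Of the 50 genes named here as called, 26 were called whichever array was left out, 20 were not called without HFD array 1, 23 without HFD array 2, 11 without chow array 1, 10 without chow array 2 and 7 without candesartan array 1, as without array 2, all with the direction kept.

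The 8 named rises ran from 4.45 to 5.75 on the log2 scale. Cck, which encodes the gut and brain peptide cholecystokinin, rose by 5.75 (adjusted p 0.000402). Since 1 of its chow arrays is at the floor, the size of the rise depends on that floor (5.14 to 6.33 over the alternatives). Atp6v0d2, a subunit of the lysosomal proton pump, rose by 5.44, Mmp12 by 5.36, Gpnmb by 5.12 and Ubd, a ubiquitin-like modifier, by 5.12 (95% CI 4.83 to 5.41, adjusted p 5.65e-07). Zranb3 rose by 4.58, Il13ra2, a decoy receptor of interleukin 13, by 4.46 with 1 chow array at the floor (3.64 to 5.29 over the alternatives), and Rgs1 by 4.45. Reep6 fell by 2.81 (adjusted p 0.00489), Cyp2f2 by 2.32 (0.0437) and Syt12 by 2.24 (0.0255). The C-type lectin Cd209d fell by 2.50 and its relative Cd209g by 2.21. Agt, which encodes angiotensinogen, the precursor of angiotensin II, fell by 2.12 (95% CI −3.08 to −1.16, adjusted p 0.0205). Gsta4, a glutathione transferase, fell by 2.11 and Ptges, a prostaglandin E synthase, by 2.02. Of these 16 genes, the calls of Cyp2f2, Syt12 and Agt ended when either HFD array or chow array 2 was left out, that of Syt12 also without chow array 1 and that of Cyp2f2 without either candesartan array. Those of Reep6, Cd209d and Cd209g ended without HFD array 2.

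**Figure D1:**
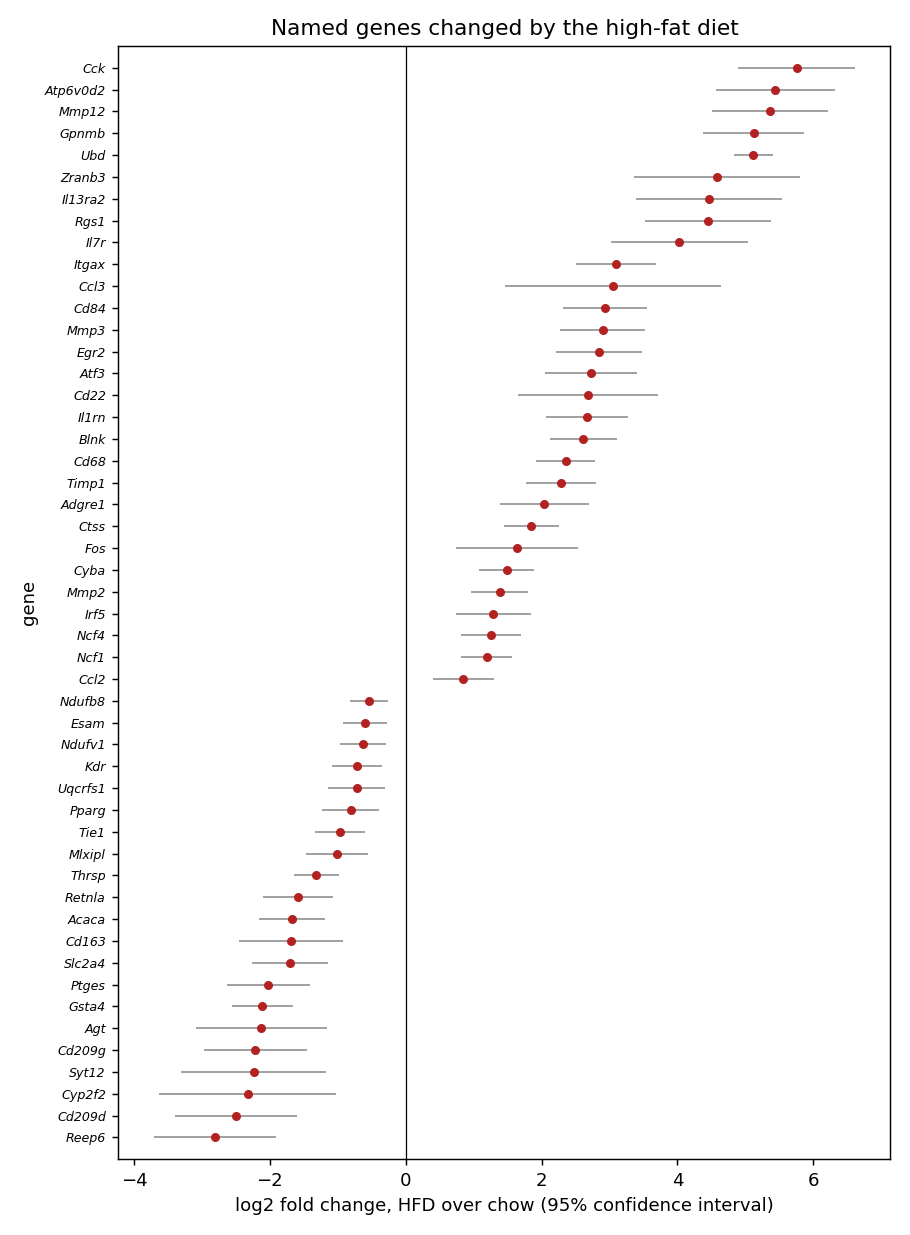
Log2 fold change of the named genes, HFD over chow (horizontal axis), with 95% confidence intervals from the limma model. The rises of lysosomal and macrophage genes reach 5.44 for Atp6v0d2, and Reep6 lies lowest at −2.81.

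Of 21 pan macrophage genes tested, 19 rose and 0 fell, and 20 rose adjusted over the list alone (median log2 change 1.56, camera adjusted p 6.81e-20). Cd84 rose by 2.94, the endosomal marker Cd68 by 2.36, Adgre1 by 2.04 (95% CI 1.39 to 2.69, adjusted p 0.00481) and Ctss, a lysosomal protease, by 1.85. Of 17 genes of lipid-laden macrophages and lysosomes, 13 rose and 0 fell, with 14 and 1 adjusted over the list alone (median 1.33, adjusted p 4.58e-15). Of 12 genes of M1 and CD11c macrophages, 4 rose and 0 fell, with 5 and 0 adjusted over the list alone (median 0.89, adjusted p 0.000669). These were Itgax (3.10, 95% CI 2.51 to 3.68), the chemokines Ccl3 (3.05, with 1 chow array at the floor; 2.27 to 3.83 over the alternatives) and Ccl2 (0.85, adjusted p 0.0355), and Irf5 (1.29), a transcription factor of inflammatory macrophages. The adjusted p with an estimated correlation between genes was 0.402 for the pan macrophage and lipid-laden lists and 0.437 for the M1 list. That test did not pass the pan macrophage list although 19 of its 21 genes were called. A list that does not pass it is therefore not shown to be unshifted. Tnf was too dim to be tested (mean signal over the 8 arrays 26.8). Also not tested were Nos2, Il6, Il12b, Cd80, Ptgs2, Ccr7, Fpr2 and Cd38. The M1 list thus does not cover these markers in any comparison. The calls of Ccl2, Ccl3, Irf5 and Adgre1 ended when either HFD array was left out, those of Ccl2 and Ccl3 also without chow array 2, that of Irf5 without chow array 1 and that of Ccl3 without either candesartan array.

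M2 macrophage genes, markers of the alternatively activated state, went both ways. Of 17, 2 rose and 6 fell (3 and 7 adjusted over the list alone), with a median of −0.0025 and camera adjusted p 0.422. Egr2 rose by 2.85 and Il1rn, the interleukin 1 receptor antagonist, by 2.67. Retnla, which encodes the secreted protein FIZZ1, fell by 1.58 (95% CI −2.10 to −1.06, adjusted p 0.00514), from a signal of 11254 ± 526 to 3852 ± 1199 (SD, n = 2 each). The scavenger receptor Cd163 fell by 1.68 (adjusted p 0.0204), a call that ended without chow array 2 or HFD array 2. The mannose receptor Mrc1 was 0.60 (adjusted p 0.295) and Arg1, which encodes arginase, 1.55 (0.255), both short of the threshold. Chil3, Il10 and Ear2 of this list were not tested.

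Other immune lists were higher by camera. Of 6 B cell genes tested, 2 rose and 0 fell, and 6 rose adjusted over the list alone (median 1.66, camera adjusted p 6.88e-05). Cd22 rose by 2.69 and Blnk, an adaptor of the B cell receptor, by 2.61. Cd79b was 1.42 (adjusted p 0.101). Of 7 MHC class II genes, limma called none singly, and 5 rose adjusted over the list alone (median 0.64, adjusted p 0.00111), with Cd74 at 0.44, H2-Eb1 at 0.81 and H2-Aa at 0.57. Of 9 T and NK cell genes, 1 rose, alone and adjusted over the list alone: Il7r, the interleukin 7 receptor, by 4.03 (list median 0.59, adjusted p 0.0274). Nkg7 was 1.09 (0.117) and Klrd1 0.59 (0.160). The list had a median of 0.35 (adjusted p 0.268) without chow array 1 and of 0.33 (0.167) without a filter, and its adjusted p ran from 0.00247 to 0.609 over the alternatives. The call of Cd22 ended when either HFD array or chow array 1 was left out. An estimated correlation brought the adjusted p to 0.402 for B cells, 0.485 for MHC class II and 0.609 for T and NK cells.

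Lists of fat synthesis and mitochondria were lower by camera, though most members were not called singly. Of 21 genes of de novo lipogenesis, 3 fell and 0 rose (6 and 0 adjusted over the list alone; median −0.48, camera adjusted p 5.10e-05). Acaca, the acetyl-CoA carboxylase that commits carbon to fat, fell by 1.67, Thrsp by 1.32 and Mlxipl, which encodes the glucose-sensing factor ChREBP, by 1.01. Without chow array 1 the median was −0.15 (adjusted p 0.157, range over the alternatives 3.44e-12 to 0.485), and without chow array 2 it was −0.84. Of 30 genes of oxidative phosphorylation and the TCA cycle, 4 fell and 0 rose (14 and 0 adjusted over the list alone; median −0.37, adjusted p 1.55e-09), all 4 in the respiratory chain: Uqcrfs1 by 0.72, Ndufv1 by 0.63, Ndufb8 by 0.53 and, named after its value was seen, Ndufs3 by 0.56. This list was at −0.22 without chow array 1 and at −0.57 without chow array 2. Of 17 adipocyte identity genes, 2 fell and 0 rose, also adjusted over the list alone: Slc2a4 by 1.70 (adjusted p 0.00514) and Pparg, the master regulator of fat cells, by 0.81 (95% CI −1.23 to −0.39, 0.0333). The adipocyte list did not pass (median −0.12, adjusted p 0.0855), but did without chow array 1 (median −0.10, 0.0206, range over the alternatives 0.0206 to 0.676). Retn was −0.997 (adjusted p 0.109) and Lep, which encodes leptin, 0.27 (0.398). Plin1, Cfd, Acsl1 and Adrb3 of the adipocyte list were not tested. The calls of Pparg, Mlxipl, Ndufb8, Ndufv1 and Uqcrfs1 ended when either HFD array or chow array 1 was left out, those of Pparg, Mlxipl and Ndufv1 also without chow array 2, and those of the 3 respiratory chain genes without either candesartan array. That of Slc2a4 ended without HFD array 1. For both lists that passed, the adjusted p with an estimated correlation was 0.485.

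By camera, matrix and stress lists were higher and the endothelial list lower, though most members were not called singly. Of 27 matrix and fibrosis genes, 6 rose and 0 fell (10 and 1 adjusted over the list alone; median 0.36, camera adjusted p 0.000138), with the proteases Mmp3 at 2.90 and Mmp2 at 1.38 and the inhibitor Timp1 at 2.29. Of 15 NADPH oxidase and antioxidant genes, 4 rose and 0 fell (5 and 2 adjusted over the list alone; median 0.20, 0.0300): the oxidase subunits Cyba (1.49), Ncf4 (1.26) and Ncf1 (1.20) and, named after its value was seen, the heme oxygenase Hmox1 (1.34). Of 13 immediate early genes, 2 rose and 0 fell (3 and 0 adjusted over the list alone; median 0.40, 0.00855), Atf3 by 2.73 and Fos by 1.64, with Junb at 1.05 (adjusted p 0.0595). Of 14 endothelial genes, 4 fell and 0 rose (9 and 0 adjusted over the list alone; median −0.52, 9.66e-06): the receptors Tie1 by 0.97 and Kdr by 0.72, Esam by 0.60 and, named after its value was seen, Emcn by 0.66. Without chow array 1 the immediate early list was at 0.14 (adjusted p 0.245, range over the alternatives 0.000503 to 0.676) and the NADPH oxidase list at 0.31 (0.157, range 0.00803 to 0.402). Without HFD array 1 the NADPH oxidase list was at 0.20 (0.0522). Without chow array 2 the matrix list was at 0.16, the immediate early list at 0.63 and the NADPH oxidase list at 0.38. The calls of Kdr, Esam, Fos, Tie1, Ncf1 and Ncf4 ended when either HFD array was left out, those of Kdr, Esam and Fos also without chow array 1, that of Kdr without chow array 2, and those of Kdr and Esam without either candesartan array. Under an estimated correlation the adjusted p was 0.437 for matrix, 0.402 for NADPH oxidase and for endothelial, and 0.676 for immediate early genes. In all, 12 of 26 lists passed camera in this comparison (9 up and 3 down), 0 with an estimated correlation and 5 with fry. Those 5 were the pan macrophage, lipid-laden, B cell, endothelial and NADPH oxidase lists.

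The other 12 lists tested did not pass in HFD against chow. The median was 0.98 for 6 mast cell genes (adjusted p 0.0942; 1 rose, Cpa3 by 1.61, and 3 adjusted over the list alone), 0.59 for 13 proliferation genes (0.0713), which lay 2.36 apart on the 2 chow arrays, with both HFD arrays between them, and −0.23 for 12 clock genes (0.119; Dbp fell by 0.64). It was 0.20 for 15 genes of the unfolded protein response (0.122; 2 rose and 1 fell, 4 and 1 adjusted over the list alone), where Sdf2l1 rose by 0.81, Hspa5 by 0.43 and Asns fell by 1.18. Of 9 genes of the renin-angiotensin system (median 0.07, 0.353) 3 rose and 2 fell: Anpep by 2.58, Mme by 0.65 and Atp6ap2 by 0.49, against Agt and Enpep (fell by 0.81). Agtr1a, which encodes the receptor both drugs block, was 0.06 (95% CI −0.32 to 0.44, adjusted p 0.869). Of 15 insulin signalling genes, Socs3 rose by 0.99 and Slc2a4, Irs1 (fell by 0.66) and Pde3b (fell by 0.54) fell, with a median of 0.02 that differs in sign from its test. In fatty acid oxidation (18 genes, median −0.14, 0.609) Pdk4 rose by 1.24 and Cpt1a by 0.51, and in the 14 PPARγ targets (−0.06) Pdk4 rose and Slc2a4 fell. Medians were 0.19 for cholesterol synthesis (13 genes, 1.26 apart on the 2 chow arrays), 0.07 for brown and beige adipocytes, and 0.07 for the interferon response and 0.0047 for mesothelial cells, both opposite in sign to their test. Too few members were measured to test the neutrophil list (3 genes, 0 rose), the skeletal muscle list (3 genes, 1 rose: Pvalb by 3.10) and the red blood cell list, whose 1 member, Alas2, fell by 1.94. The list members given here beyond the named genes were chosen after their values were seen.

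**Figure D2:**
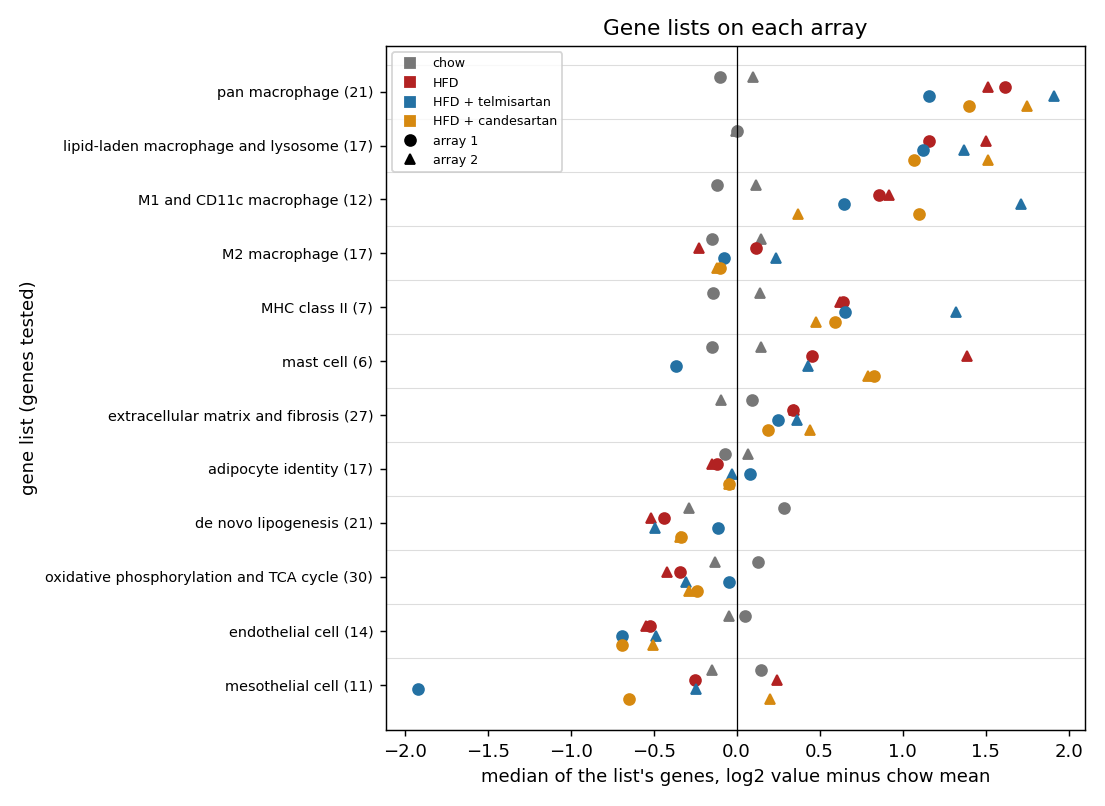
Median log2 signal of 12 gene lists on each array, minus the chow mean (horizontal axis; circle, array 1; triangle, array 2 of each group). Pan macrophage genes lie at 1.62 and 1.51 with HFD and at 1.16 and 1.91 with telmisartan.

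The second comparison, telmisartan with HFD, asks whether telmisartan changed the obese fat, and its macrophages in particular. By camera, metabolic gene lists were higher with telmisartan, by medians of 0.14 to 0.26 on the log2 scale, and mast cell, mesothelial and immediate early lists were lower. None of these calls held with an estimated correlation (adjusted p 0.560 to 0.744), and without telmisartan array 1 the adipocyte list was at 0.036, mast cells at −0.17 and mesothelium at −0.18. The adipocyte list was no higher than random lists of equally bright genes (percentile 42.2). The pan macrophage list did not pass, as the 2 arrays went opposite ways: against chow it was at 1.16 and 1.91 with telmisartan and at 1.62 and 1.51 with HFD. The signal of Adgre1 was 2623 ± 1245 with telmisartan (SD, n = 2), against 2631 ± 2.31 with HFD. The M2 genes Retnla, Clec10a and Mgl2 lay higher with telmisartan, at log2 changes of 0.94, 0.70 and 0.89. The M2 list did not pass (median 0.27, and 0.074 without telmisartan array 1). No gene passed the test across all genes.

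limma called 0 of 11232 genes, at all 8 omissions of an array too, and 696 had an unadjusted p under 0.05, against 562 by chance. The smallest adjusted p was 0.766. Genes whose arrays do not overlap made up 37.9%, against 33.3% by chance. The genes with the smallest p were Depp1 (1.07, 95% CI 0.64 to 1.51), Ms4a8a (1.36) and the chemokine Ccl8 (1.74, 95% CI 0.999 to 2.47) among those higher, and Adarb1 (−2.11), Zbed6 (−1.08) and Cd163l1 (−1.40) among those lower. None of them passed.

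Of the macrophage lists none passed. The M2 list had a median of 0.27 (17 genes, camera adjusted p 0.111; limma called 0 over all genes, and 2 rose adjusted over the list alone). Without HFD array 1 it was 0.30 (0.00930, range over the alternatives 0.00930 to 0.716), without HFD array 2 0.15, without telmisartan array 1 0.074 and without telmisartan array 2 0.12. Retnla was 0.94 (95% CI 0.43 to 1.46), Clec10a, a galactose lectin, 0.70 (0.28 to 1.13), its neighbour Mgl2 0.89 (0.10 to 1.68), Cd163 0.76 (−0.0024 to 1.52), Mrc1 0.12 and Arg1 0.46. The M1 list had a median of −0.022 (adjusted p 0.815), opposite in sign to its test. Its members also differed: Itgax was −0.62 (95% CI −1.20 to −0.03), Ccl2 0.01 (−0.43 to 0.46), and the interferon-induced chemokines Cxcl9 and Cxcl10 were 1.08 and 0.56. The pan macrophage list had a median of −0.0011 (0.982), also opposite in sign to its test, with Adgre1 at −0.09 (95% CI −0.74 to 0.56), Msr1 at −0.49, Fcgr1 at 0.39 and Cybb at −0.35. Among random lists of equally bright genes the percentile was 100 for the M2 list, 56.5 for the M1 list and 3.73 for the pan macrophage list. The macrophage medians turned on which telmisartan array was used. Without array 1 the pan macrophage list was at 0.30 (6.86e-11) and the M1 list at 0.40 (0.00237). Without array 2 the pan macrophage list was at −0.36 (2.19e-05, range over the alternatives 6.86e-11 to 0.996; M1 0.00237 to 0.989). Between the 2 telmisartan arrays, 21 of 21 pan macrophage genes were lower on array 1, by a median of −0.75.

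The metabolic lists were higher with telmisartan, with 0 genes called singly by limma and 0 adjusted over the list alone. Of 30 genes of oxidative phosphorylation and the TCA cycle, 29 were higher (median 0.21, camera adjusted p 1.65e-08), with Atp5o at 0.39, Cox5b at 0.38 and Cox4i1 at 0.29. Lipogenesis was at 0.26 (19 of 21 genes higher, 0.000964), with Dgat1 at 0.37, Pgd at 0.34 and Thrsp at 0.27. Adipocyte identity was at 0.14 (15 of 17 higher, 0.00215), with Pparg at 0.34 (95% CI −0.07 to 0.76), Gpd1 at 0.29, Cidec at 0.21, Adipoq at 0.07 and Lep at 0.07. PPARγ targets were at 0.21 (0.00703), with the fatty acid carrier Fabp4 at 0.13, and fatty acid oxidation at 0.19 (13 of 18 higher, 0.0291), with Cpt2 at 0.32, Decr1 at 0.31 and Acaa2 at 0.29. The probe sets of Gpd1, Dgat1 and Fabp4 differ in sign. Without telmisartan array 1 the medians were 0.12 for lipogenesis (adjusted p 0.250), 0.036 for adipocyte identity (0.536), 0.10 for PPARγ targets (0.368), 0.089 for oxidative phosphorylation (0.0269) and 0.10 for fatty acid oxidation (0.394), which was also at 0.15 (0.321) without HFD array 2. Without telmisartan array 2 adipocyte identity was at 0.24 and oxidative phosphorylation at 0.34. With quantile normalization the medians were 0.12 for lipogenesis (0.147), 0.038 for adipocyte identity (0.871), 0.10 for PPARγ targets (0.587), 0.10 for fatty acid oxidation (0.298) and 0.10 for oxidative phosphorylation (0.0529). Cyclic loess gave 0.010 for adipocyte identity (0.797), 0.12 for lipogenesis (0.0933) and 0.10 for oxidative phosphorylation (0.00431). On telmisartan array 1 bright genes lay higher as a whole: of 3 equal classes by brightness, the brightest was at 0.093 and the dimmest at −0.12 from the mean of all arrays. Among random lists of equally bright genes, the adipocyte list had percentile 42.2, and the lowest of the other 4 was 99.2. Over all alternatives the adjusted p ran from 6.09e-06 to 0.751 for lipogenesis, 0.000504 to 0.871 for adipocyte identity, 0.00332 to 0.716 for PPARγ targets, 0.00397 to 0.756 for fatty acid oxidation and 3.50e-10 to 0.716 for oxidative phosphorylation. With an estimated correlation it was 0.697, 0.697, 0.560, 0.744 and 0.697 in that order.

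Genes of the unfolded protein response were higher in 13 of 15 cases (median 0.20, camera adjusted p 0.000104; 0.230 with an estimated correlation), with the chaperone partners Dnajb9 at 0.44 and Manf at 0.41 and Herpud1 at 0.38. This list passed whichever array was left out. MHC class II genes were at 0.39 (6 of 7 higher, 0.00369), with H2-DMa at 0.71, H2-Ab1 at 0.66 and H2-Eb1 at 0.52. They were at 0.09 (0.563) without telmisartan array 2, at 0.69 without telmisartan array 1 at 0.31 (0.0691) with quantile normalization and at 0.24 (0.0683) with cyclic loess, with a range over the alternatives of 1.20e-09 to 0.716. With an estimated correlation the adjusted p was 0.697. For both lists limma called 0 genes, and 0 adjusted over the list alone.

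Mast cell genes were lower in 6 of 6 cases (median −0.85, adjusted p 0.00116), with the mast cell protease Cma1 at −1.10, Cpa3 at −0.96 and Mcpt4 at −0.74, and 1 fell adjusted over the list alone. All 11 mesothelial genes, markers of the lining of the fat pad, were lower (median −1.01, 0.000227), with Upk1b at −1.38, Bnc1 at −1.36 and Msln at −1.13. All 13 immediate early genes were lower (median −0.38, 0.000964), with Nr4a1 at −1.04, Klf2 at −0.54 and Junb at −0.51. Of 12 clock genes 10 were lower (median −0.34, 0.0101), with Ciart at −0.66 and Nr1d2 at −0.49 but Cry1 at 0.59. Adjusted over the list alone limma called 0 genes of the last 3 lists. Without telmisartan array 1 the medians were −0.17 for mast cells (adjusted p 0.250), −0.18 for mesothelium (0.383) and −0.12 for immediate early genes (0.348), and without telmisartan array 2 the last 2 were at −1.97 and −0.61. Mast cells were at −0.47 without HFD array 2. The clock list kept most of its size but not its call, at −0.27 (0.0751) without telmisartan array 1 and −0.36 (0.158) without HFD array 2, and was at −0.22 with a filter at the 70th percentile. Over all alternatives the adjusted p ran from 2.99e-05 to 0.716, 2.20e-07 to 0.716, 1.28e-05 to 0.716 and 0.00262 to 0.716 in that order. With an estimated correlation it was 0.697 for the first 3 lists and 0.560 for the clock.

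In all, 11 of 26 lists passed camera in telmisartan against HFD (7 up and 4 down), 0 with an estimated correlation and 0 with fry. The rest had medians of 0.04 for lipid-laden macrophages and lysosomes and 0.02 for the NADPH oxidase list (both opposite in sign to their test), 0.17 for T and NK cells, −0.26 for B cells, −0.05 for insulin signalling, −0.02 for the matrix list, −0.22 for the renin-angiotensin list (0.263), −0.04 for endothelial cells, −0.0057 for brown and beige adipocytes (mean and median differ in sign), 0.05 for the interferon response, −0.16 for proliferation and 0.19 for cholesterol synthesis (0.111). Agt was 0.46 and Agtr1a −0.22. The untested lists were at 0.39 for neutrophils, 0.29 for skeletal muscle (1 up and 1 down adjusted over the list alone) and 0.24 for Alas2 of red blood cells.

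**Figure D3:**
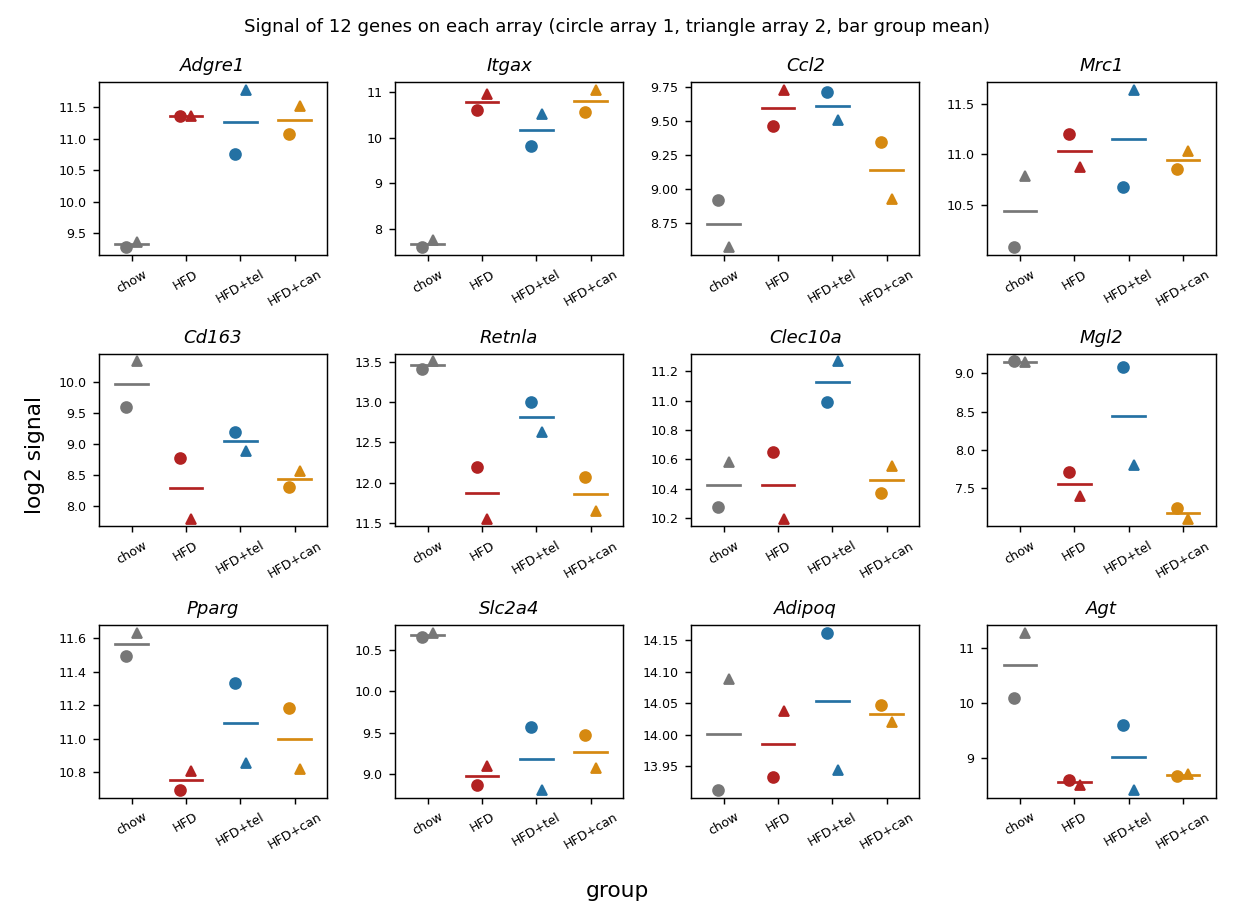
Log2 signal of macrophage, adipocyte and renin-angiotensin genes on each array (vertical axis; bar, mean of the 2 arrays of a group). Retnla has means of 13.46 with chow, 11.88 with HFD, 12.82 with telmisartan and 11.86 with candesartan.

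The third comparison, candesartan with HFD, asks the same of the other receptor blocker. By camera, oxidative phosphorylation and fatty acid oxidation lists were slightly higher with candesartan, and endothelial and immediate early lists lower. None of these calls held with an estimated correlation (adjusted p 0.639 to 0.895), and the immediate early list was at 0.076 without candesartan array 1. No focal macrophage list passed: Adgre1 had a signal of 2553 ± 539 and Itgax of 1805 ± 427 (SD, n = 2 each), against 2631 ± 2.31 and 1774 ± 302 with HFD. Ccl2, the monocyte chemokine, was 570 ± 116 against 777 ± 99.5. No gene passed the test across all genes.

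limma called 0 of 11232 genes, also whichever array was left out, and 140 had an unadjusted p under 0.05, against 562 by chance. The smallest adjusted p was 1.0. Genes without overlap made up 33.4%, against 33.3% by chance. The low count of small p may come from the spread that all groups share. The 2 arrays differed by an SD of 0.273 for HFD and 0.314 for candesartan, but 0.445 for chow and 0.484 for telmisartan. The shared spread makes the test strict here, so calling 0 genes does not show that candesartan changed none. Smallest p values were those of Igkv6-20, an antibody gene (2.47), Armc1 (0.56) and Abcd3, a peroxisomal transporter (0.52), among genes higher with candesartan, and of Igha (−1.67), Zfp420 (−1.55) and Zbed6 (−0.83) among those lower. None of them passed.

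The focal macrophage lists had medians of −0.05 (pan macrophage, camera adjusted p 0.350), −0.04 (M1, 0.475) and −0.07 (M2, 0.368), and limma called 0 of their genes, as it did adjusted over the list alone for every list. Among random lists of equally bright genes, which vary less than genes that move together, their percentiles were 0.08, 24.2 and 1.27 in that order. Without candesartan array 2 the pan macrophage list was at −0.13 (0.00397, range over the alternatives 0.00397 to 0.993), and without HFD array 2 the M2 list was at −0.17 (0.0181, range 0.0181 to 0.993). Adgre1 was −0.06 (95% CI −0.71 to 0.59), Itgam −0.28, Cd14 −0.23 and Csf1r −0.11. Ccl2 was −0.46 (−0.90 to −0.01), Cxcl9 0.42, Ccr2 −0.15 and Itgax 0.02. Mgl2 was −0.38, Egr2 −0.30, Gas6 −0.15, Cd163 0.15, Mrc1 −0.09 and Arg1 0.20.

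Oxidative phosphorylation and TCA cycle genes were higher in 28 of 30 cases (median 0.12, adjusted p 6.63e-06), with Cycs at 0.25, Idh3a at 0.22 and Cox4i1 at 0.17, and passed whichever array was left out. Fatty acid oxidation genes were higher in 17 of 18 cases (median 0.12, 0.00204), with Ehhadh at 0.49, the carnitine carrier Slc25a20 at 0.37 and Acadl at 0.22. Adipocyte identity was at 0.07 (15 of 17 higher, 0.0389), with Slc2a4 at 0.29, Pparg at 0.25, Gpd1 at 0.23, Adipoq at 0.05 and Lep at 0.01, and PPARγ targets at 0.09 (0.0457). Endothelial genes were at −0.13 (12 of 14 lower, 0.00386), with Kdr at −0.38 (95% CI −0.74 to −0.02), Flt1 at −0.37 and Egfl7 at −0.29. Immediate early genes were at −0.29 (11 of 13 lower, 0.000452), with Ier3 at −0.55, Btg2 at −0.47 and Klf2 at −0.29. Without HFD array 1 the medians were 0.04 for adipocyte identity (0.201), 0.05 for PPARγ targets (0.109) and −0.09 for endothelium (0.109), and 0.21 for fatty acid oxidation. Without HFD array 2 they were 0.06 for fatty acid oxidation (0.253), 0.10 for PPARγ targets (0.0788) and −0.20 for endothelium. Without candesartan array 1 they were 0.01 for adipocyte identity (0.688), 0.06 for PPARγ targets (0.363), −0.06 for endothelium (0.363) and 0.076 for immediate early genes (0.496). Without candesartan array 2 adipocyte identity was at 0.16 and immediate early genes at −0.68. Cyclic loess gave 0.019 for adipocyte identity (0.311) and 0.036 for PPARγ targets (0.296). Over all alternatives the adjusted p ran from 2.74e-09 to 0.993 for oxidative phosphorylation, 0.000122 to 0.993 for fatty acid oxidation, 0.00110 to 0.993 for adipocyte identity, 0.00496 to 0.993 for PPARγ targets, 0.000517 to 0.993 for endothelium and 4.28e-15 to 0.993 for immediate early genes. Under an estimated correlation it was 0.639 for PPARγ targets and endothelium and 0.895 for the other 4 lists.

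In all, 6 of 26 lists passed camera in candesartan against HFD (4 up and 2 down), 0 with an estimated correlation and 0 with fry. Agt was 0.14 and Agtr1a −0.25. The rest had medians of 0.12 for lipogenesis (0.0518), 0.28 for brown and beige adipocytes (0.0828), 0.11 for the unfolded protein response (0.0795), 0.16 for cholesterol synthesis, 0.03 for the interferon response, −0.04 for T and NK cells, −0.29 for B cells (0.205), −0.14 for mast cells (0.234), −0.04 for MHC class II, −0.03 for matrix genes, −0.02 for the renin-angiotensin list, −0.19 for mesothelium (0.197), −0.12 for the clock, −0.02 for proliferation and −0.05 for NADPH oxidase. Insulin signalling (0.0044) and lipid-laden macrophages (0.01) were opposite in sign to their test. The untested lists were at 0.08 for neutrophils, −0.15 for skeletal muscle and 0.17 for Alas2.

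The fourth comparison sets telmisartan against candesartan at the same dose and time, and asks whether telmisartan, which the study's title links to macrophage polarization, differed from another blocker of the same receptor. In structure, telmisartan carries a carboxylic acid on its biphenyl where candesartan carries a tetrazole. By camera, the M2 and MHC class II lists were higher with telmisartan than with candesartan, and mast cell and mesothelial lists lower, calls that did not hold with an estimated correlation (adjusted p 0.679, 0.679, 0.993 and 0.993). Of 17 M2 genes 4 lay higher on both telmisartan arrays than on both candesartan arrays, and the MHC class II list was at 0.13 without telmisartan array 2. Retnla had a signal of 7286 ± 1322 with telmisartan and 3749 ± 752 with candesartan, and Mgl2 of 383 ± 226 and 145 ± 9.55 (SD, n = 2 each). Over all genes tested no single gene passed between the drugs: Adgre1 differed by −0.03 (95% CI −0.68 to 0.62) and Pparg by 0.09 (−0.32 to 0.51).

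limma called 0 of 11232 genes, also whichever array was left out, and 550 had an unadjusted p under 0.05, against 562 by chance. Genes without overlap made up 32.2%, against 33.3% by chance. The smallest adjusted p was 0.484, for Cd163l1 (−1.99, 95% CI −2.59 to −1.40), and the next was 0.924. Other genes with small p were Ccl8 (1.55, 95% CI 0.82 to 2.29), Depp1 (1.04) and Fcrls (0.96), higher with telmisartan, and Pls3 (−0.76) and Prss23 (−0.76), lower. None of them passed.

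The M2 list was higher with telmisartan in 12 of 17 cases (median 0.27, camera adjusted p 0.0233; 0.679 with an estimated correlation), with 3 genes adjusted over the list alone: Mgl2 at 1.27 (95% CI 0.48 to 2.06), Retnla at 0.96 (0.44 to 1.48) and Clec10a at 0.67 (0.24 to 1.09). Cd163 was 0.61 (−0.16 to 1.37), Arg1 0.27 and Mrc1 0.21. The list was at 0.05 (0.0796) without telmisartan array 2 and at 0.12 (0.174) without candesartan array 1, with a range over the alternatives of 0.00584 to 0.987. The pan macrophage list was at 0.01 (adjusted p 0.551), with Aif1 at 0.56, Msr1 at −0.38 and C1qb at 0.25. It was at 0.39 (4.01e-12) without telmisartan array 1, −0.28 (5.49e-05) without telmisartan array 2 and 0.17 (0.0250) without candesartan array 2 (range 4.01e-12 to 0.993). The M1 list was at 0.06 (0.489), with Itgax at −0.63 (95% CI −1.21 to −0.05), Cxcl10 at 0.62 and Ccl2 at 0.47 (0.02 to 0.92), and at 0.54 (0.000488, range 0.000488 to 0.993) without telmisartan array 1. Adjusted over the list alone limma called 0 of the pan macrophage, M1 and adipocyte genes.

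Adipocyte identity was at 0.08 (adjusted p 0.174), with Cidec at 0.17, Fabp4 at 0.14, Pck1 at −0.60, Adipoq at 0.02 (95% CI −0.23 to 0.27) and Lep at 0.06. It was at 0.17 (0.00825) without telmisartan array 2 and at 0.13 (0.0284) without candesartan array 1 (range 0.00825 to 0.993). MHC class II genes were higher with telmisartan in 6 of 7 cases (median 0.42, 0.000702), with H2-DMa at 0.69, H2-Ab1 at 0.68 and H2-Eb1 at 0.57. Genes of the unfolded protein response were higher in 11 of 15 cases (median 0.19, 0.00926), with Sdf2l1 at 0.43, Herpud1 at 0.42 and Hspa5 at 0.20, and those of oxidative phosphorylation in 25 of 30 (median 0.09, 0.0118), with Ndufv2 at 0.24, Cox5b at 0.21 and Uqcrb at 0.18. The latter median lay near the middle of random lists of equally bright genes (percentile 55.1). Mast cell genes were at −0.72 (0.0239), with Cma1 at −1.13, Cpa3 at −0.85 and Mcpt4 at −0.72, and 1 was lower adjusted over the list alone, against 0 in the other 4 lists of this paragraph that passed. Mesothelial genes were at −0.91 (9 of 11 lower, 0.00926), with Bnc1 at −1.48, Lrrn4 at −1.04 and Msln at −0.98.

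Each of these 5 calls ended without 1 or more of the arrays. Without telmisartan array 1 the medians were −0.031 for mast cells (adjusted p 0.868), 0.075 for mesothelium (0.868) and −0.027 for oxidative phosphorylation (0.727), and 0.97 for MHC class II. Without telmisartan array 2 they were 0.13 for MHC class II (0.273) and 0.18 for the unfolded protein response (0.0884), which kept its size, and −1.22 for mast cells, −1.82 for mesothelium and 0.23 for oxidative phosphorylation. Without candesartan array 2 they were −0.74 for mast cells (0.0799), −0.51 for mesothelium (0.416) and 0.13 for the unfolded protein response (0.0857). With quantile normalization oxidative phosphorylation was at 0.01 (0.986), mast cells at −0.59 (0.0522) and the unfolded protein response at 0.14 (0.0657). With all probe sets the unfolded protein response was at 0.058 (0.105), and with cyclic loess oxidative phosphorylation was at 0.016 (0.664). Over all alternatives the adjusted p ran from 0.000920 to 0.993 for mast cells, 1.11e-06 to 0.993 for mesothelium, 5.28e-05 to 0.993 for oxidative phosphorylation, 4.97e-10 to 0.987 for MHC class II and 0.00392 to 0.841 for the unfolded protein response. Camera with an estimated correlation gave 0.993 for the first 3 of these, 0.679 for MHC class II and 0.651 for the unfolded protein response, so 0 of the 6 lists that passed (4 up and 2 down) held, and 0 held with fry. Agt was 0.32 and Agtr1a 0.03. The rest had medians of 0.30 for T and NK cells (0.0775), 0.09 for lipogenesis (0.0775), 0.07 for PPARγ targets, 0.07 for endothelial cells, 0.15 for cholesterol synthesis, −0.00088 for lipid-laden macrophages, −0.02 for insulin signalling, −0.04 for the renin-angiotensin list, −0.24 for brown and beige adipocytes (0.148; 1 lower adjusted over the list alone), −0.08 for immediate early genes, −0.21 for the clock (0.0875) and −0.11 for proliferation. The medians of B cells (−0.15), fatty acid oxidation (0.02), matrix (0.02), interferon response (−0.0043) and NADPH oxidase (−0.07) differ in sign from their mean or test. The untested lists were at 0.31 for neutrophils, 0.44 for skeletal muscle and 0.07 for Alas2.

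Last, both drug groups were compared with chow, as the study's own fold changes were, to see how far the diet pattern stood under treatment. By camera, the pan macrophage, lipid-laden and M1 lists stayed above chow and the endothelial list below, with 6 of 14 endothelial genes called lower with each drug. No list held with an estimated correlation, whose smallest adjusted p was 0.216 with telmisartan and 0.271 with candesartan. The M2 list did not pass (medians −0.026 and 0.011, adjusted p 0.974 and 0.284). Telmisartan on HFD differed from chow in 948 genes (557 higher and 391 lower) and candesartan on HFD in 740 (503 and 237). With telmisartan 18 of 21 pan macrophage genes were above chow (median 1.499), and with candesartan 16 (median 1.46). Lipid-laden macrophage genes were at 1.14 and 1.29, M1 genes at 1.13 and 0.71, and MHC class II genes at 0.95 and 0.54, telmisartan first. Endothelial genes were at −0.60 and −0.61, and lipogenic genes at −0.23 and −0.31, with 4 and 3 of 21 called lower. The chow arrays themselves differ in the lipogenic list (0.28 and −0.28), and telmisartan array 1 lay between them at −0.11. The unfolded protein response was at 0.35 and 0.31, the clock at −0.51 and −0.47, and with telmisartan the mesothelial list was at −1.08. Single arrays differ in some of these: the mesothelial list was at −1.92 and −0.24 on the telmisartan arrays, the M1 list at 0.64 and 1.71 with telmisartan and as low as 0.37 on candesartan array 2, and MHC class II at 0.65 and 1.32 with telmisartan.

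At an unadjusted p under 0.05 limma gave 2769 genes for telmisartan on HFD and 2391 for candesartan on HFD, against 562 by chance. For telmisartan the count was 531 without chow array 2, 533 without HFD array 1, 528 without HFD array 2, 1683 without telmisartan array 1, and 593 without candesartan array 1, as without array 2. For candesartan it was 461 and 460 without chow arrays 1 and 2, 394 and 392 without HFD arrays 1 and 2, 1306 and 1315 without telmisartan arrays 1 and 2, and 248 and 117 without candesartan arrays 1 and 2. Camera passed 14 lists for telmisartan on HFD and 12 for candesartan on HFD, and 0 with an estimated correlation.

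The diet-called genes were largely shared. Of the 578 rises and 331 falls with HFD, 425 and 197 were also called with telmisartan on HFD (28.7 and 11.5 by chance), and 467 and 180 with candesartan on HFD (25.9 and 6.98 by chance). All 3 comparisons with chow shared 391 rises and 140 falls, and 0 genes were called in opposite directions. Chance here is that of independent draws. The comparisons also use the same chow arrays, which can add shared calls. In 100 simulations of groups unchanged from chow at most 1 call was shared, but such groups give hardly any calls. That count thus cannot tell how many shared calls the common chow arrays add here. The 2 changes also covaried over all genes, at 0.2702 for telmisartan and 0.286 for candesartan, against a simulated mean of 0.0295.

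Whether the drugs moved the diet-called genes back toward chow was measured over all 909 of them. Of the 909 diet-called genes, 634 (69.7%) had a telmisartan effect opposite to the diet's, and 639 (70.3%) a candesartan effect. With telmisartan the 578 diet-raised genes moved by a median of −0.13 and the 331 diet-lowered genes by 0.13, against diet medians of 1.25 and −0.91. With candesartan these were −0.05 and 0.12. The HFD arrays shared by both comparisons produce opposite signs without any effect: unchanged groups gave 62.7% (59.7% to 65.3% in 100 simulations) and a covariance of −0.0301 (−0.0345 to −0.0250). The covariance was −0.0475 for telmisartan and −0.0319 for candesartan, the latter within the simulated range. The simulations treat genes as independent, which makes their range narrower than that of real arrays. They also give a gene 1 spread in all groups, yet the 2 arrays differed by an SD of 0.273 for HFD, 0.445 for chow and 0.484 for telmisartan. With the smaller HFD spread the shared arrays would give less, so the simulated share and covariance may be overstated. The simulated range thus does not decide whether candesartan reversed the diet effect. With separate HFD arrays for the 2 effects the share was 67.9% and 69.2% for telmisartan, and 60.6% and 52.2% for candesartan. These shares are over the fewer diet genes called with 1 HFD array, not over the 909. When an array was left out, the diet genes were called anew, so these shares too are over other sets than the 909. For telmisartan the share was 36.6% without telmisartan array 1 and 84.2% without telmisartan array 2. For candesartan it was 44.1% without candesartan array 1 and 83.6% without candesartan array 2. Over the 909 genes, single arrays 1 and 2 gave 82.3% and 39.1% with telmisartan and 82.4% and 47.9% with candesartan.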

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

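Of the tests in this part, that of array scaling and brightness on the telmisartan arrays was written before its result was seen, and the other tests were chosen after the results they measure were seen.

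Macrophage genes were lower on telmisartan array 1 than on telmisartan array 2, in 21 of 21 pan macrophage genes and by a median of −0.75 on the log2 scale. The other macrophage lists varied. Against chow the M1 list was at 0.64 and 1.71 on arrays 1 and 2, and the lipid-laden list at 1.12 and 1.37. The M2 list was at −0.076 and 0.24, with members that went both ways between these arrays. Array scaling or brightness is argued against, since the median was −0.80 after quantile normalization and −0.84 after cyclic loess. Admixture of chow tissue, or an exchange with it, does not by itself account for 9 of 11 mesothelial genes that lay below all 4 chow and HFD arrays on telmisartan array 1. The mesothelial list also differed between the candesartan arrays (−0.65 and 0.20 against chow), so admixture in a piece with little mesothelium is not excluded. A lower share of all cells other than adipocytes by 1 common factor is argued against by the endothelial list, which differed by only −0.19. A lower share of other cells by amounts that differ between cell types may stand behind the pattern. Under the main scaling, the 6 lists of endothelial, matrix, T and NK, B, mast and mesothelial cells were all lower on array 1. The nearest to 0 was matrix at −0.094, and the test of 1 common factor was added after this value was seen. Since this explanation allows any amount of decrease per list, its test could hardly speak against it and does not decide. The M2 list, also of cells other than adipocytes, was not among the 6. A real difference between these 2 mice, or in their response to telmisartan, stays open and untested, as each array is 1 mouse.

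M2 macrophage genes were higher with telmisartan than with candesartan (median 0.27, camera adjusted p 0.0233), a difference between the effects of 2 drugs at the same dose that did not hold with an estimated correlation (0.679) or fry (0.987). Array scaling or brightness is argued against, since the median was 0.27 after quantile normalization and 0.28 after cyclic loess, although the adjusted p after the former was 0.0522 (range over the alternatives 0.00584 to 0.987), with the median as large as before. A single array could account for much of it, since the median was 0.055 without telmisartan array 2. It also fell without candesartan array 1, so no 1 array is singled out. Against chow the M2 list was at −0.076 and 0.24 on telmisartan arrays 1 and 2, with members that went both ways between these arrays. An effect of the drug itself stays open: 4 of 17 genes were higher on both telmisartan arrays than on both candesartan arrays and 1 was lower on both, where chance gives 16.7% each way. With 2 mice per drug the tables do not decide between them.

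Genes changed by the diet lay back toward chow with telmisartan, in 69.7% of 909 genes. The share with candesartan was 70.3%, and simulated unchanged groups gave 62.7% (59.7% to 65.3%). The HFD arrays that both comparisons share are argued against as the whole cause for telmisartan, since with separate HFD arrays for the 2 effects the lower of the 2 shares was 67.9%. For candesartan these shares were 60.6% and 52.2%. Telmisartan array 1 alone may account for it, since the share was 36.6% without that array and 84.2% without telmisartan array 2. Candesartan had the same kind of split, at 44.1% without candesartan array 1 and 83.6% without candesartan array 2. Shares with separate HFD arrays or without an array are over the diet genes called anew, not over the 909. An effect of telmisartan in 1 mouse and not the other stays open and untested, as does a factor shared by the arrays numbered 1.

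The difference between telmisartan and candesartan also passed camera for 5 other lists, none of which held with an estimated correlation (adjusted p 0.651 to 0.993). The mast cell list was at −0.72, and at −0.031 without telmisartan array 1. The MHC class II list was at 0.42, and at 0.13 without telmisartan array 2. The oxidative phosphorylation and TCA cycle list was at 0.092, percentile 55.1 among random lists of equally bright genes, and at −0.027 without telmisartan array 1. The mesothelial list was at −0.91, and at 0.075 without telmisartan array 1. The list of the unfolded protein response was at 0.19, at 0.13 without candesartan array 2 and at 0.058 with all probe sets.

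Outside the genes tested, limma called 41 of 2809 probe sets that have no gene symbol or several in HFD against chow (34 higher and 7 lower), and 0 of them in the other 3 comparisons.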

How the results depend on the processing

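Cyclic loess normalization, separate HFD arrays, the shares of single arrays and all alternatives for lists other than the 4 focal ones were chosen after the data were seen; the others given here were set beforehand.

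Of 1253 alternative values of 63 named genes in HFD against chow, 1100 stayed on their side of the threshold, 130 lost a call, 23 gained one and 0 reversed. Most of these genes were named for a large change or a small p in the same data. A reversal was therefore hardly possible, and its absence does not test the direction of the diet effect. In the drug comparisons 0 named genes were called by limma under any of 1091, 776 and 836 alternative values. Signal over background limits genes near the floor, and 2 arrays per group limit the rest. The cause of each change below was not tested unless the alternative itself states it.

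At an adjusted p under 0.10 the counts were 1544 for HFD against chow, 1618 for telmisartan on HFD and 1243 for candesartan on HFD against chow. With no test but 2-fold in all 4 pairs of arrays they were 407, 252 and 349, and 6 for telmisartan against HFD, 4 for candesartan against HFD and 5 for telmisartan against candesartan. Without a filter, which adds genes at the floor, they were 174, 332 and 164, and 4, 6 and 6. With only the 2 groups compared the counts were 1189 for HFD against chow, 198 for telmisartan on HFD and 844 for candesartan on HFD. The covariance for candesartan was −0.0752 without a filter.

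With an estimated correlation and with fry the medians are those of the main test. Camera with an estimated correlation passed 0 lists in any comparison, so it does not separate shifted lists from unshifted ones here. The pan macrophage list in HFD against chow kept its call with fry. Calls ended with an estimated correlation for the pan macrophage list (1.56, adjusted p 0.402) and the M1 list (0.89, 0.437; fry 0.114) in HFD against chow, the adipocyte list with telmisartan (0.14, 0.697; fry 0.716) and candesartan (0.074, 0.895; fry 0.993) against HFD, and the M2 list between the drugs (0.27, 0.679; fry 0.987). For the adipocyte list with telmisartan, quantile normalization gave 0.038 (0.871) and cyclic loess 0.010 (0.797). For the adipocyte list with candesartan, quantile normalization gave 0.066 (0.212), no filter 0.074 (0.134), the 70th percentile 0.074 (0.0526), no trend 0.074 (0.0992), all probe sets 0.071 (0.120) and cyclic loess 0.019 (0.311). For the M2 list between the drugs, quantile normalization gave 0.27 (0.0522), no filter 0.27 (0.120), the 70th percentile 0.21 (0.0675) and all probe sets 0.27 (0.0531). In HFD against chow the adipocyte list passed with only the 2 groups (−0.12, 0.0479) and with all probe sets (−0.11, 0.0416).

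Leaving out each array in turn gave 165 to 1611 genes for HFD against chow, 528 to 1683 for telmisartan on HFD and 117 to 1315 for candesartan on HFD against chow, and 0 in the 3 drug comparisons. In HFD against chow the lists ranged over 1.49 to 1.64 (pan macrophage), 0.83 to 0.93 (M1), −0.23 to 0.12 (M2) and −0.15 to −0.019 (adipocyte). In telmisartan against HFD they ranged over −0.36 to 0.30, −0.24 to 0.40, 0.074 to 0.30 and 0.036 to 0.24. In candesartan against HFD they ranged over −0.13 to 0.10, −0.13 to 0.022, −0.17 to 0.092 and 0.014 to 0.16. Between the drugs they ranged over −0.28 to 0.39, −0.24 to 0.54, 0.055 to 0.31 and −0.046 to 0.17. Without telmisartan array 2 the pan macrophage list was lower by camera (−0.36 against HFD, −0.28 against candesartan), where the test over all arrays pointed up without passing. Against HFD its median over all arrays was already just under 0 (−0.0011), and 0.30 without telmisartan array 1. Reversed without telmisartan array 1 were oxidative phosphorylation (−0.027, range −0.027 to 0.23) and mesothelium (0.075, range −1.82 to 0.075) between the drugs, and without candesartan array 1 immediate early genes against HFD (0.076, range −0.68 to 0.076).

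With each array left out in turn and the diet genes called anew, the reversal share ranged over 36.6% to 84.2% for telmisartan. For candesartan it ranged over 44.1% to 83.6%. The covariance then ranged over −0.115 to 0.020 and −0.0575 to −0.0130. Over the same 909 genes as the main share, single arrays gave 82.3% and 39.1% with telmisartan and 82.4% and 47.9% with candesartan. The share thus differs by array. With separate HFD arrays the shares were 67.9% and 69.2% for telmisartan, and 60.6% and 52.2% for candesartan. The covariances were −0.0255 and −0.0325 for telmisartan, and −0.0111 and −0.0156 for candesartan.

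A replicate block, which treats the numbers of the labels as pairs, gave 1280 genes for HFD against chow, 1220 for telmisartan on HFD, 973 for candesartan on HFD, and 0 in the drug comparisons.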

Other observations

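The tests in this part, on 380 families of genes grouped by their symbols, were all chosen after the data were seen. Among the 40 results that passed camera in the 4 comparisons, 0 medians changed sign under any of the 4 scalings. They were selected for passing in the same arrays, so a change of sign was hardly possible and its absence does not test their direction. Camera with an estimated correlation passed 0 of the 40, at adjusted p of 0.966 or more.

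In HFD against chow, families of innate immunity and tissue remodelling were higher. Toll-like receptors, which sense microbial products, had a median of 1.19 on the log2 scale over 9 genes (camera adjusted p 0.000695), and limma called 3: Tlr13 at 3.40, Tlr1 at 1.92 and Tlr8 at 1.88. Matrix metalloproteinases were at 1.16 over 8 genes (0.00414), with 5 called: Mmp12, Mmp3, Mmp2, Mmp14 at 1.03 and Mmp11 at 1.29. CXC chemokines were at 1.12 over 8 genes (0.00372), with Cxcl14 at 1.97, Cxcl12 at 1.40 and Cxcl16 at 1.21 called. Of 12 receptors of the TNF family (median 0.58, 0.00414), 4 were called: Tnfrsf11a at 1.48, Tnfrsf12a at 1.23, Tnfrsf13b at 1.22 and Tnfrsf1b at 1.13. The Cd209 lectins, carried by macrophages and dendritic cells, went the other way, at −1.84 over 5 genes (0.00181), with Cd209d, Cd209g and Cd209f (fell by 1.84) called. Mitochondrial ribosomal proteins were at −0.26 over 47 Mrpl genes (0.000695) and −0.32 over 29 Mrps genes, of which Mrps15 fell by 0.65. Of 9 genes with Sox symbols (−0.51), which include the transcript Sox6os, Sox7 fell by 1.17, Sox13 by 0.91 and Sox18, a factor of blood vessel cells, by 0.86.

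In the drug comparisons limma called 0 genes of any family. The Cd209 lectins lay higher with telmisartan, at 0.81 against HFD (camera adjusted p 0.0367; 0.81 to 0.92 over the scalings) and 0.81 against candesartan (0.0173), with Cd209d at 1.12 and 0.81, Cd209g at 0.81 and 0.93, and Cd209a at 0.86 and 0.90. CC chemokines were at 0.40 over 13 genes in telmisartan against candesartan (0.00180; 0.40 to 0.46 over the scalings), with Ccl8 at 1.55 and Ccl12 at 1.43. Mitochondrial ribosomal genes of the Mrpl family were at 0.23 in telmisartan against HFD, 0.10 in candesartan against HFD and 0.15 between the drugs. Proteasome subunits of the Psmb family were at 0.32 in telmisartan against HFD and 0.21 between the drugs. Genes with Rpl symbols were at 0.17 in telmisartan against HFD but at 0.03 after quantile normalization, and 234 Zfp genes at −0.19 but −0.01 after it.

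The telmisartan arrays also differed from each other in lists beyond macrophages. On array 1 the median was lower than on array 2 by −1.71 for mesothelial genes (10 of 11 lower), −1.04 for the interferon response (12 of 13), −0.94 for mast cells (6 of 6), −0.87 for T and NK cells (7 of 9), −0.77 for B cells (6 of 6) and −0.71 for MHC class II (7 of 7). It was higher by 0.42 for cholesterol synthesis (13 of 13) and by 0.22 for oxidative phosphorylation (29 of 30), but the latter by 0.10 (25 of 30) after quantile normalization and 0.074 (21 of 30) after cyclic loess. The mast cell median was −0.69 (4 of 6) and −0.83 (5 of 6) after these. For the M2 list the median of the members' differences was −0.03 (9 of 17 lower), and 0.067 and 0.070 after them. Its median against chow was −0.076 on array 1 and 0.24 on array 2.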
